A study of Mus musculus with 42 samples.

How the data were processed

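Liver RNA of male C3HeB/FeJ mice was measured on Affymetrix whole-transcript arrays. The 42 arrays fell into 4 groups by the labels: 18 control arrays of mice on a low-fat diet, aged 15 to 17 weeks, and 8 arrays each after 7, 14 and 21 days of a high-fat diet (HFD), at 15, 16 and 17 weeks of age. The labels describe single-housed, random-fed mice. They number the replicates of a group without saying which animal each came from, so the p-values measure the spread between these samples, part of which may be technical.

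Per the labels' protocols, RNA was extracted with a miRNeasy kit including DNase digestion, and biotin-labelled targets were prepared with the WT Sense Target Labeling Assay. The deposited values are on the log2 scale; per the submitters' processing notes the authors used RMA (background correction, normalization and summarization of probes) in Affymetrix Expression Console 1.1. The genome build behind the array annotation is not given in the sources used here, so no coordinates are printed. The value table held 32624 probe sets. One probe set lacked a value on 33 arrays and was left out of the tests. It had a value on the control arrays numbered 1 to 9 only. Whether these were processed apart from the other arrays is not given in the labels and was not tested. Array medians ran from 3.08 to 3.28, so the scale was close to common across arrays, and no step of scaling was added. Other scalings moved the counts of rises and falls, as given below. Arrays carry no read depth, so the number of arrays and the signal over background limit the precision. The 929 olfactory receptor genes, taken as a background level, had a median log2 value of 2.28 and a 95th percentile of 2.86, and 67.5% of genes lay above that percentile. No array was a copy of another: the smallest SD of the log2 difference between 2 arrays was 0.255, and at most 0.049% of values were equal.

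Gene symbols came from the platform annotation. Of the probe sets, 19559 had 1 gene symbol, 1469 had several and 11596 had none listed, and only the first kind was named. Entrez identifiers matched a RefSeq gene table (assembly GRCm38.p6, used for names alone) for 19475 of them, and 0 symbols needed an update. A gene with more than 1 probe set (841 genes) was represented by the brightest. This left 17989 genes, with no filter on dim ones. Probe sets of near-identical family members, such as the Cyp4a, Cyp2b and Acot genes, can hybridise to each other's transcripts.

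All 42 arrays entered 1 fit with 4 groups in limma 3.58.1 (lmFit and eBayes, R 4.3.3), so that the groups shared an estimate of the spread per gene. Contrasts compared each HFD time with the controls and the HFD times with each other, and an F test asked for any difference among the 3 HFD times. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison were called. Tests were 2-sided.

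There were 37 gene lists, written from textbook knowledge. Each was tested against all other genes with camera (preset inter-gene correlation 0.01), with the adjusted p taken over the lists of a comparison. Camera with an estimated correlation and fry were run beside it; fry asks whether the genes of a list move one way on balance and does not compare them with other genes. Lists shared some members, among them 4 of the lipogenesis and elongation lists and 4 of the PPAR-alpha and peroxisomal lists. Beside each list stand its measured members, how many passed over all genes, and how many passed with the p adjusted over the list alone.

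Genes were named by a rule: for each comparison with controls the 6 largest rises and 6 largest falls in log2 among called genes, and up to 2 called members of each list that passed, those with the largest change in its direction; between HFD times the 4 largest rises and falls. A panel of 20 genes was named whatever its result. Predicted or unnamed genes, small RNA genes and the Mup, Olfr, Vmn and antigen receptor families were passed over for the largest changes. Of the panel, 16 genes were measured, and the others were not analysed here. The groups, contrasts, lists, naming rule and most other settings were fixed before the data were examined. Other list members are named as examples of their list.

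Comparisons with the same 18 controls share chance values. Their overlap was set beside 100 simulations, in which unchanged groups were drawn from whole arrays of residuals, beside the overlap of independent lists, and beside fits in which each comparison had its own 9 controls (odd or even numbers). For each fitted comparison, 100 splits of the arrays into groups of the same sizes were drawn, the real one included. Between HFD times 100 more were drawn within the arrays numbered 1 to 4 and 5 to 8, a step chosen after the data were seen.

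The fits were tested on simulated data for 7 days of HFD against controls, with 17989 genes and known changes. Values were normal noise drawn with each gene's real mean and pooled variance. Genes therefore varied independently, unlike on the real arrays. The simulation cannot show how often genes or lists are called through variation that genes share. Of 100 genes changed 1.5-fold, 89% were recovered, and of 100 changed 2-fold, 99%. Among the calls, 7.39% were unchanged genes, and 0 of the 33 lists without a changed gene were called. With no gene changed at 14 days, 0 genes were called.

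The fits were repeated under other settings, chosen beforehand: eBayes with trend and robust settings, only the arrays of the groups compared, removal of the dimmest genes (those with a mean under 2.89), quantile normalization, median centring, array weights, the replicate number as a block, the mean of a gene's probe sets, a minimum fold of 1.5, removal of arrays that stood apart, each array left out in turn, camera with an estimated correlation and fry. Settings chosen after the data were seen were the Malat1 level as a covariate, HFD arrays numbered 1 to 4 or 5 to 8 alone with all controls, that number set as a covariate, and the mean of the acinar markers as a covariate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.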

Results

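The study followed the liver transcriptome of C3HeB/FeJ mice, an inbred strain, through the early weeks of a high-fat diet (HFD), and its title places membrane lipid and mitochondrial membrane changes before hepatic insulin resistance. Transcripts were measured on 42 arrays: 18 from controls on a low-fat diet and 8 each after 7, 14 and 21 days of HFD. Controls were pooled over their days of feeding and their age (15 to 17 weeks), whereas the HFD groups were 15, 16 and 17 weeks old, so age and time on the diet rose together. The titles of the control and 21-day arrays, and of no other group, carry the word reanalysis. A batch that follows this word cannot be told apart from the groups in the comparisons of 7 and 14 days with controls or of 21 days with the other HFD times, since the 7-day and 14-day arrays lie wholly on its other side. It does not bear on 21 days against controls, where both groups carry the word. At 7 and 21 days 97 genes were called in the same direction, with 0 in opposite directions, though against the same 18 controls. With the controls split, the shared genes numbered 58 and 64. For genes not called at 21 days, among them 124 called at 7 days alone, such a batch cannot be told apart from the diet. The controls numbered 1 to 9 were the only arrays with a value for 1 probe set. Had they been processed apart, this would bear on every comparison with controls, and it was not tested. The median SE of a log2 difference was 0.09 against controls and 0.11 between HFD times.

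Levels of pancreatic acinar markers and of Malat1 varied between arrays within every group. The mean of 13 pancreatic acinar markers, digestive enzymes of the exocrine pancreas, ran from 3.41 to 8.55 over the controls (median 4.58). It ran from 3.55 to 9.55 at 7 days (median 5.49), from 3.51 to 9.33 at 14 days (5.70) and from 3.40 to 6.62 at 21 days (4.27). The nuclear RNA Malat1 averaged 8.02 ± 1.24 (SD, n = 18) in controls and 7.92 ± 1.22, 7.58 ± 1.57 and 8.18 ± 1.35 (n = 8 each) at 7, 14 and 21 days. Within each HFD group, Malat1 was higher on all arrays numbered 5 to 8 than on all arrays numbered 1 to 4.

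**Figure D1:**
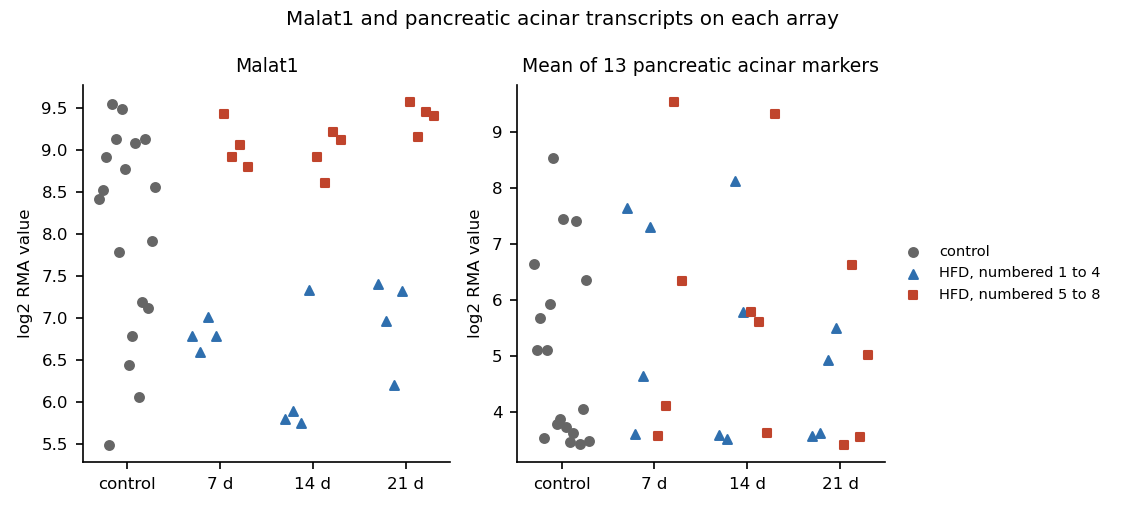
Log2 RMA value of Malat1 (left) and mean log2 RMA value of 13 pancreatic acinar markers (right) on each of the 42 arrays, by group; each symbol is 1 array, and symbols of HFD arrays show their number in the labels. Malat1 ran from 5.49 to 9.54 over the controls and separated the HFD arrays numbered 5 to 8 (mean 9.13) from those numbered 1 to 4 (mean 6.65); the acinar mean varied within every group.

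The first comparison asked which transcripts differed from controls after 7 days of HFD. Cyp4a14, a fatty acid omega-hydroxylase, was 12.4-fold higher: its log2 value was 6.66 ± 0.76 (SD, n = 8) against 3.02 ± 0.32 (n = 18) in controls, and all 8 HFD arrays lay above every control (log2 change 3.64, SE 0.26, limma adjusted p = 6.22e-14). Mfsd2a, a transporter of lysophosphatidylcholine, rose 8.69-fold, Vnn1, a pantetheinase, 8.13-fold, Cyp4a31 7.20-fold, Rgs16, a regulator of G-protein signalling, 6.68-fold and Cyp4a10 5.88-fold. The falls were smaller. Serpina4-ps1, a serpin pseudogene, was 3.54-fold lower, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, 2.40-fold lower (8 of 8 arrays below the control mean). Acmsd, which diverts tryptophan breakdown away from NAD synthesis, was 2.23-fold lower, Etnppl, an ethanolamine-phosphate phospho-lyase, 2.19-fold lower, the growth factor receptor Egfr 1.95-fold lower and Obp2a, an odorant-binding lipocalin, 1.93-fold lower.

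Genes of fatty acid breakdown rose together at 7 days. Of 26 measured targets of the nuclear receptor PPAR-alpha, 21 rose and 0 fell (24 rose adjusted over the list alone), with a median log2 change of 0.85 and a camera adjusted p of 2.65e-83. Beside the Cyp4a genes and Vnn1 they included the hormone gene Fgf21 (log2 1.12, 2.18-fold, adjusted p = 4.58e-06), the lipid droplet coat gene Plin2 (log2 1.06) and the acyl-CoA thioesterase genes Acot1 (log2 0.93), Acot2, Acot3 (log2 1.07) and Acot4. Mitochondrial fatty acid oxidation had 9 of 18 members higher and 0 lower (14 higher adjusted over the list alone, median 0.43, camera adjusted p = 2.51e-29), among them Bdh1, which interconverts ketone bodies (log2 0.75), and Hadhb of the trifunctional protein (log2 0.70). Peroxisomal oxidation had 7 of 15 higher and 0 lower (11 adjusted over the list alone, median 0.33, camera adjusted p = 1.13e-23), led by the transporter gene Abcd2 (log2 1.89, 3.72-fold) and by Crat, carnitine acetyltransferase (log2 1.19). With an estimated correlation the 3 lists still passed, at adjusted p = 5.36e-12, 1.47e-05 and 2.55e-05.

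Lipid synthesis genes were also higher at 7 days. In de novo lipogenesis 9 of 18 members rose and 0 fell (13 adjusted over the list alone, median 0.77, adjusted p = 0.0126 with an estimated correlation). Examples were the fatty acid desaturase gene Fads2 (log2 1.33, SE 0.18), the glycerol-3-phosphate acyltransferase gene Gpam (log2 1.16) and Acaca, acetyl-CoA carboxylase (log2 0.98). In fatty acid elongation and desaturation 5 of 13 rose and 0 fell (6 adjusted over the list alone, median 0.40, adjusted p = 0.0158 with an estimated correlation): Fads2, Fads1 (log2 0.99), Elovl5 (log2 0.96), Elovl2 (log2 0.95) and Hacd3 (log2 0.40). Glycerophospholipid synthesis had 4 of 45 higher and 0 lower (5 adjusted over the list alone, median 0.06, adjusted p = 0.0397 with an estimated correlation), namely Gpam, the phosphatidate phosphatases Lpin2 (1.99-fold) and Lpin1 (log2 0.88), and Agpat3 (log2 0.42). Among lipid droplet and uptake genes 6 of 24 rose and 0 fell (11 rose and 1 fell adjusted over the list alone, median 0.16, adjusted p = 7.97e-04 with an estimated correlation), led by the fatty acid translocase gene Cd36 (log2 1.89, SE 0.30) and Plin2. Sphingolipid metabolism had 2 of 24 higher (3 adjusted over the list alone), Kdsr (log2 0.67) and the ceramide synthase gene Cers6 (log2 0.55). Its camera call (adjusted p = 0.00183) had an adjusted p = 0.134 with an estimated correlation. In cholesterol synthesis and uptake 1 of 17 rose, Mvd (log2 0.60, 2 adjusted over the list alone). Its camera call (adjusted p = 1.13e-05) had an adjusted p = 0.174 with an estimated correlation.

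Among genes of the mitochondrial membrane, 2 carriers rose at 7 days. The inner membrane carriers Slc25a47 (log2 1.02, SE 0.10, adjusted p = 2.29e-10) and Slc25a20, the carnitine-acylcarnitine carrier (log2 0.55), were called among 38 carrier and import genes, with 0 lower (5 adjusted over the list alone, median 0.13, adjusted p = 0.0205 with an estimated correlation). Of 71 genes for respiratory complexes I to IV and ATP synthase, 0 passed limma's test at 7, 14 or 21 days, and 2, 2 and 0 had an unadjusted p under 0.05. Their median log2 changes were 0.05, -0.02 and -0.03, and the 95% limits lay within 1.5-fold either way for 70, 70 and 71 of them. At 7 days the camera adjusted p for complex I was 0.0927, for complexes II to IV 0.0812 and for ATP synthase 0.215. At 21 days preset camera called complex I lower, a call that did not hold with an estimated correlation, as given below. In the tricarboxylic acid cycle 1 of 19 rose, Suclg1 (log2 0.38, 3 adjusted over the list alone). Its camera call (adjusted p = 3.21e-05) had an adjusted p = 0.0622 with an estimated correlation.

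**Figure D2:**
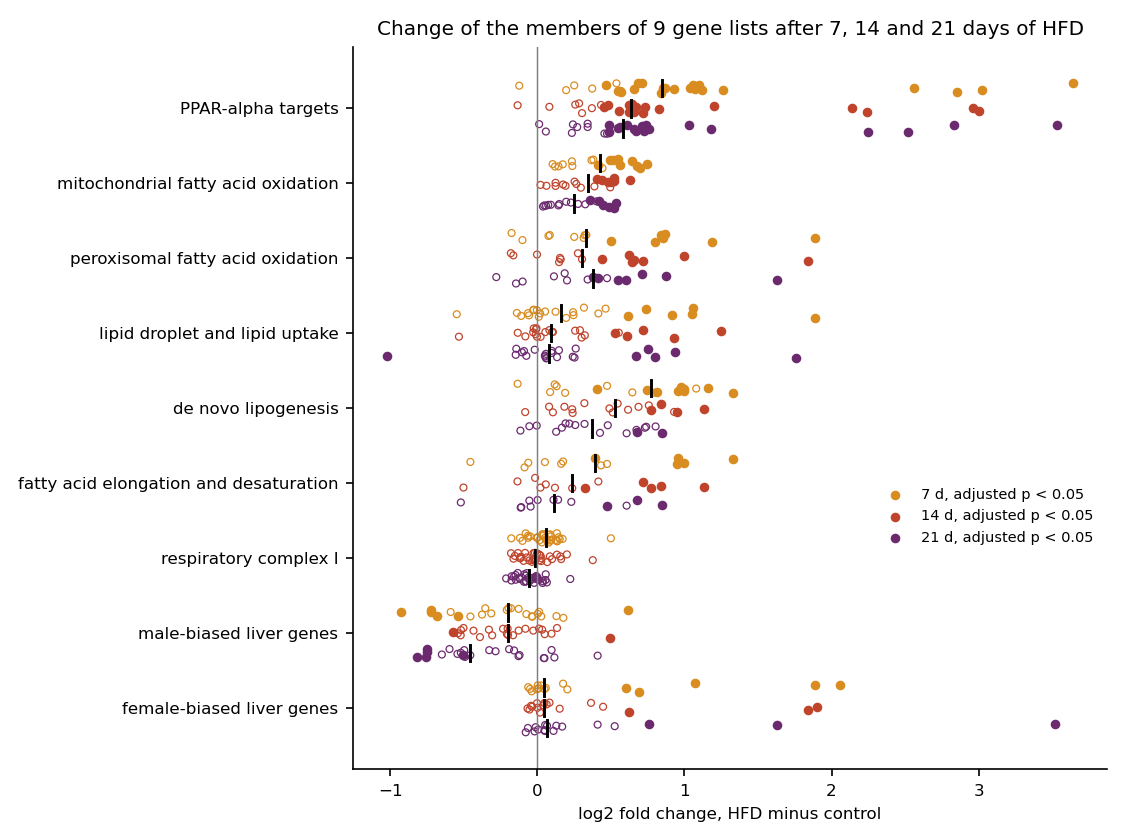
Log2 fold change against controls (horizontal axis) of each measured member of 9 gene lists after 7, 14 and 21 days of HFD; filled points passed limma's test at an adjusted p under 0.05, open points did not, and black bars mark medians. PPAR-alpha targets had medians of 0.85, 0.64 and 0.59, whereas members of respiratory complex I clustered near 0 with none called.

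Among other groups at 7 days, genes more abundant in female liver rose in 5 of 17 and fell in 0 (5 adjusted over the list alone, adjusted p = 0.00201 with an estimated correlation): Cyp2b9, a female-biased cytochrome P450 (log2 2.06), Abcd2, Acot3, Cyp3a44 and Rtn4. The control mean of Cyp2b9 (2.67) lay under the background percentile of 2.86, so the size of its change at each HFD time may be understated. Male-biased genes fell in 5 of 23 and rose in 1, Ces2e (7 and 1 adjusted over the list alone, median -0.20, adjusted p = 0.0441 with an estimated correlation), with Cyp7b1, an oxysterol hydroxylase, at -0.93 and the steroid dehydrogenase gene Hsd3b5 at -0.73. Markers of Kupffer cells and macrophages rose in 3 of 18, Vsig4 (log2 0.64), C1qc (log2 0.46) and Cd68 (log2 0.44), and fell in 0 (6 adjusted over the list alone, median 0.14, adjusted p = 0.0174 with an estimated correlation). Vsig4 and C1qc lost their calls after quantile normalization, and the list had no camera call at 14 or 21 days. In gluconeogenesis and glycolysis 2 of 18 rose, Pklr, liver pyruvate kinase (log2 0.74), and Gys2, liver glycogen synthase (log2 0.60, 5 adjusted over the list alone). Its camera call (adjusted p = 6.30e-06) had an adjusted p = 0.0669 with an estimated correlation. The insulin signalling (2 rose adjusted over the list alone), circadian clock, interferon response and acinar lists had camera calls (adjusted p = 0.0333, 0.0123, 0.0439 and 0.00822) and no called member over all genes. These had adjusted p = 0.453, 0.256, 0.453 and 0.589 with an estimated correlation. The acinar median change was 0.77. After quantile normalization the insulin signalling call ended at 7 days (adjusted p = 0.399) and at 14 days (0.179), as did the clock call (0.0716 and 0.0763) and at 7 days the interferon call (0.118). With median centring the insulin signalling (0.107 and 0.0727) and acinar calls (0.0957 and 0.0503) ended at 7 and 14 days, and the interferon call (0.0987) at 7 days. Lcn2, lipocalin 2, and Hp, haptoglobin, rose among 23 acute phase genes (camera adjusted p = 0.0531). Among 17 NRF2 targets Me1 rose and Gsta4 fell (camera adjusted p = 0.945).

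In all, 251 genes passed at 7 days (208 higher, 43 lower), 38 of them at 2-fold or more, while 1669 had an unadjusted p under 0.05 where chance gives 899. Of the 37 lists 19 passed (18 up, 1 down), 11 of them also with an estimated correlation and 14 by fry. Cyp7a1 lost its call without HFD 7 days replicate 4 (log2 -0.97, adjusted p = 0.0792), as did Hsd3b5 without replicate 2 (adjusted p = 0.0721), Egfr (0.0575) and Vsig4 (0.136) without 5 or 7, Pklr without 1 or 2 (0.0678), C1qc without 4, 5, 6 or 7 (0.0965), Gys2 without 1, 2, 3, 6 or 8 (0.0847), Mvd without any of 1 to 6 (0.122), and Serpina4-ps1 without any of 13 arrays, 8 of them controls (0.148), each the largest of its values. The number of genes was 144 with the HFD arrays numbered 5 to 8 alone, 250 with those numbered 1 to 4, and 605 with array weights. Of the named genes, 6 had changes that differed more than 1.5-fold between the arrays 1 to 4 and 5 to 8. Those not called in both were Serpina4-ps1 (log2 -2.63 with adjusted p = 0.00871, and -1.02 with 0.646), Egfr (-0.62 with 0.243, and -1.30 with 0.0118) and Mvd (0.90 with 0.00216, and 0.31 with 0.715). Those called in both were Cyp4a14 (3.14 and 4.14), Mfsd2a (3.42 and 2.81) and Cd36 (1.42 and 2.37). Other named genes, with changes closer together, also lost their call with fewer arrays. Among them were Fads1 (log2 0.79, adjusted p = 0.302) and Gpam (0.95 with 0.121) in the arrays 5 to 8, and Obp2a (-0.68 with 0.265) in 1 to 4.

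**Figure D3:**
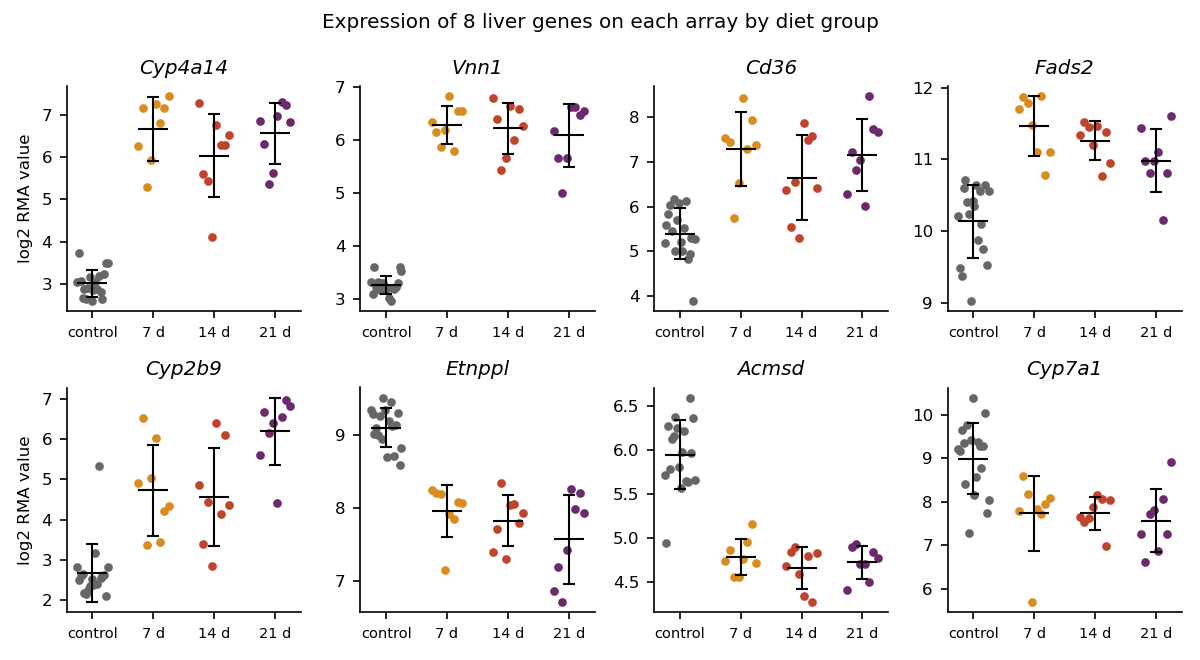
Log2 RMA value (vertical axis) of 8 genes on each of the 42 arrays, by group; points are arrays, and bars give the mean ± SD (n = 18 controls, 8 per HFD time). Cyp4a14, Vnn1, Cd36, Fads2 and Cyp2b9 lay higher and Etnppl, Acmsd and Cyp7a1 lower at each HFD time than in controls; Cyp4a14 and Vnn1 lay above every control on all HFD arrays.

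After 14 days the rises had the same leading genes. Cyp4a14 was 8.02-fold higher (log2 6.03 ± 0.98, SD, n = 8, against 3.02 ± 0.32, n = 18; limma adjusted p = 4.59e-11), Vnn1 7.79-fold (all 8 arrays above every control), Rgs16 6.84-fold, Mfsd2a 5.72-fold, Cyp4a31 4.71-fold and Cyp4a10 4.42-fold. Obp2a was 2.75-fold lower, Acmsd 2.44-fold, Etnppl 2.41-fold and Cyp7a1 2.39-fold lower. Akr1c19, an aldo-keto reductase, was 1.76-fold lower and Ddc, aromatic amino acid decarboxylase, 1.70-fold lower, each below the control mean on 8 of 8 arrays.

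PPAR-alpha targets rose in 19 of 26 at 14 days (22 adjusted over the list alone, median 0.64, adjusted p = 1.21e-11 with an estimated correlation), with Fgf21 at log2 0.83 and Plin2, Acot1 to Acot4 and the Cyp4a genes again among them. Mitochondrial fatty acid oxidation rose in 7 of 18 (9 adjusted over the list alone, median 0.34, adjusted p = 4.84e-05 with an estimated correlation), with Bdh1 at 0.63 and Acadl, long-chain acyl-CoA dehydrogenase, at 0.52. Peroxisomal oxidation rose in 7 of 15 (9 adjusted over the list alone, median 0.30, adjusted p = 4.84e-05 with an estimated correlation), with Abcd2 at 1.84 and Decr2, a peroxisomal dienoyl-CoA reductase, at 0.72. De novo lipogenesis rose in 4 of 18 (11 adjusted over the list alone, median 0.53, adjusted p = 0.0233 with an estimated correlation): Fads2 (log2 1.13), Gpam (log2 0.95), Fads1 (log2 0.84) and Elovl5 (log2 0.78). Elongation and desaturation rose in 5 of 13 (5 adjusted over the list alone, median 0.24, adjusted p = 0.0352 with an estimated correlation). Lipid droplet and uptake genes rose in 5 of 24 (6 rose and 1 fell adjusted over the list alone, median 0.09, adjusted p = 0.00354 with an estimated correlation), among them Cd36 (log2 1.25, SE 0.30) and Mgll, monoacylglycerol lipase (log2 0.93). Female-biased genes rose in 3 of 17, Cyp2b9 (log2 1.90), Abcd2 and Acot3 (5 adjusted over the list alone, adjusted p = 0.00747 with an estimated correlation). Without Cyp2b9 and the members shared with the PPAR-alpha and lipid lists, the 13 left had a median of 0.04. Their p was 0.106 by camera with an estimated correlation, a test chosen after the results were seen. No member of these 7 lists fell over all genes.

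The other 10 lists with a camera call at 14 days lost it with an estimated correlation. Carriers and import rose in 3 of 38, Slc25a47 (log2 0.66), Slc25a30 (log2 0.75) and Slc25a20 (4 rose and 1 fell adjusted over the list alone, adjusted p = 0.0886 with an estimated correlation). Male-biased genes fell in 1, the complement gene C8b (log2 -0.58), and rose in 1, Ces2e, of 23 (6 and 1 adjusted over the list alone, median -0.20, adjusted p = 0.083 with an estimated correlation). Glycerophospholipid synthesis rose in 1 of 45, Gpam (4 adjusted over the list alone, adjusted p = 0.0926), sphingolipid metabolism in 1 of 24, Kdsr (log2 0.46, 1 adjusted over the list alone, adjusted p = 0.293), and the tricarboxylic acid cycle in 1 of 19, Suclg1 (log2 0.37, 2 adjusted over the list alone, adjusted p = 0.355), each p with an estimated correlation. Cholesterol synthesis, gluconeogenesis and glycolysis, insulin signalling, the clock and the acinar markers had 0 called members by limma over all genes. Their adjusted p were 0.355, 0.355, 0.524, 0.355 and 0.577 with an estimated correlation, and the acinar median change was 0.64.

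At 14 days 120 genes passed (91 higher, 29 lower), 19 of them at 2-fold or more, and 1079 had an unadjusted p under 0.05 where chance gives 899. Of the lists 17 passed (16 up, 1 down), 7 also with an estimated correlation and 8 by fry. Single arrays ended the calls of Cd36 (without HFD 14 days replicate 3, 5, 6 or 7, adjusted p up to 0.145), Cyp7a1 (1, 2, 3 or 7; up to 0.107), Fads1 (5 or 7; up to 0.0596), Kdsr (any of 3 to 8; up to 0.114) and Slc25a30 (any of 26 arrays; up to 0.187). The number of genes was 69 with the HFD arrays numbered 1 to 4 alone, 58 with those numbered 5 to 8, and 193 with array weights. Cd36 (log2 0.55, adjusted p = 0.606) and Cyp2b9 (log2 1.22, adjusted p = 0.337) were not called with the numbers 1 to 4 and rose with 5 to 8 (1.95 with 0.00126, and 2.58 with 0.00193). Cyp4a14 (2.57 and 3.43), Rgs16 (2.40 and 3.14) and Abcd2 (1.54 and 2.14) rose with both, by amounts more than 1.5-fold apart.

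After 21 days Cyp4a14 was 11.6-fold higher (log2 6.56 ± 0.73, SD, n = 8, against 3.02 ± 0.32, n = 18; limma adjusted p = 2.59e-13), and Cyp2b9 was 11.5-fold higher, at 6.19 ± 0.83 against 2.67 ± 0.72 (log2 change 3.52, SE 0.37, adjusted p = 7.17e-09), with 7 of 8 arrays above every control. The control mean of Cyp2b9 lay under the background percentile of 2.86, so its fold is uncertain and may be understated. Vnn1 was 7.13-fold, Mfsd2a 5.98-fold, Cyp4a31 5.73-fold and Cyp4a10 4.75-fold higher. Serpina4-ps1 was 3.71-fold lower, Etnppl 2.87-fold, Cyp7a1 2.69-fold, Acmsd 2.33-fold, Obp2a 2.10-fold and Lpl, lipoprotein lipase, 2.03-fold lower.

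PPAR-alpha targets rose in 17 of 26 at 21 days and fell in 0 (23 adjusted over the list alone, median 0.59, adjusted p = 3.71e-11 with an estimated correlation), with Fgf21 at log2 1.03. Mitochondrial fatty acid oxidation rose in 6 of 18 (10 adjusted over the list alone, median 0.25, adjusted p = 9.40e-04 with an estimated correlation), with Bdh1 at 0.53 and Decr1, dienoyl-CoA reductase, at 0.52. Peroxisomal oxidation rose in 7 of 15 (10 rose and 1 fell adjusted over the list alone, median 0.38, adjusted p = 6.06e-04 with an estimated correlation), with Abcd2 at 1.63 and Crat at 0.88. Lipid droplet and uptake genes rose in 5 of 24, among them Cd36 (log2 1.76) and G0s2, an inhibitor of triglyceride lipase (log2 0.94), and 1 fell, Lpl (log2 -1.02, 5 and 1 adjusted over the list alone, adjusted p = 0.0296 with an estimated correlation). Male-biased genes fell in 5 of 23 and rose in 0 (14 fell and 1 rose adjusted over the list alone, median -0.46, adjusted p = 7.89e-04 with an estimated correlation): Cyp7b1 (log2 -0.82), Gstp1, a glutathione transferase (log2 -0.76), C8b (log2 -0.75), C6 (log2 -0.75) and Mup21 (log2 -0.51). Female-biased genes rose in 3 of 17, Cyp2b9, Abcd2 and Acot3 (5 adjusted over the list alone, median 0.07, adjusted p = 9.40e-04 with an estimated correlation).

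Of the lists whose camera call at 21 days was lost with an estimated correlation, lipogenesis rose in 2 of 18, Fads2 (log2 0.85) and Elovl5 (log2 0.68, 8 adjusted over the list alone, median 0.37, adjusted p = 0.157 with an estimated correlation). Elongation rose in 3 of 13, with Elovl2 (5 adjusted over the list alone, adjusted p = 0.323), carriers and import in 2 of 38, Slc25a47 (log2 0.67) and Slc25a20 (log2 0.49, 2 adjusted over the list alone, adjusted p = 0.323), and glycerophospholipid synthesis in 0 of 45 (3 adjusted over the list alone, adjusted p = 0.312), each p with an estimated correlation. Of the NRF2 targets, genes of the oxidative stress response, 2 of 17 fell, the glutathione transferases Gsta4 (log2 -0.59) and Gstm3 (log2 -0.80, 4 adjusted over the list alone, adjusted p = 0.157 with an estimated correlation). The unfolded protein response fell in 1 of 24, Asns, asparagine synthetase (log2 -0.65, 1 adjusted over the list alone, adjusted p = 0.312 with an estimated correlation). Acute phase proteins fell in 1 of 23, Orm1 (log2 -0.56, 2 fell and 1 rose adjusted over the list alone, adjusted p = 0.181 with an estimated correlation). Respiratory complex I (median -0.06), the endothelial markers (median -0.08) and the acinar markers (median -0.50) were called lower as lists, with camera adjusted p = 0.0271, 0.0178 and 0.0242 and 0 members called by limma. Their adjusted p were 0.609, 0.48 and 0.728 with an estimated correlation, and the complex I call also ended after quantile normalization (adjusted p = 0.562). So did those of the unfolded protein response (0.143), acute phase proteins (0.0759) and acinar markers (0.0853, and 0.114 with median centring).

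At 21 days 126 genes passed (80 higher, 46 lower), 21 of them at 2-fold or more, and 1198 had an unadjusted p under 0.05 where chance gives 899. Of the lists 16 passed (9 up, 7 down), 6 also with an estimated correlation and 6 by fry. Single arrays ended the calls of Asns (without HFD 21 days replicate 3, 5, 6, 7 or 8, adjusted p up to 0.0962), Gstm3 (any of 9 arrays; up to 0.162 without replicate 6) and Serpina4-ps1 (any of 18 arrays; up to 0.166). With the HFD arrays numbered 1 to 4 alone 903 genes passed, and the majority of calls turned to lower (417 higher, 486 lower), whereas with those numbered 5 to 8 349 passed (213 higher, 136 lower). Serpina4-ps1 fell with the numbers 1 to 4 (log2 -3.00, adjusted p = 0.0026) and was not called with 5 to 8 (log2 -0.78, adjusted p = 0.512), and G0s2 rose with 1 to 4 (log2 1.37) and was not called with 5 to 8 (log2 0.51, adjusted p = 0.239). Changes called with both sets and more than 1.5-fold apart were those of Etnppl (log2 -2.05 and -1), Cyp4a14 (3.01 and 4.06), Vnn1 (2.36 and 3.31), Abcd2 (1.15 and 2.11) and Cd36 (1.44 and 2.08).

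The panel held genes of lipid, glucose and insulin metabolism reported whatever their result. Beside Cyp4a14, Cd36, Cyp7a1 and Fgf21, which passed at all 3 times, 12 measured panel genes did not pass limma's test at any time. Fasn, fatty acid synthase, stood 2.12-fold, 1.91-fold and 1.75-fold above controls at 7, 14 and 21 days with adjusted p = 0.0686, 0.337 and 0.49, and its 95% limits at 7 days ran from 0.46 to 1.70 in log2. The lipogenic regulator Srebf1 differed by 0.13, 0.32 and 0.26 in log2 (adjusted p = 0.904, 0.964 and 0.965), and the desaturase gene Scd1 by 0.47, 0.24 and -0.05 (0.245, 0.962 and 0.995). Of the glucose genes, Pck1 differed by 0.27, 0.21 and 0.06 and G6pc by 0.40, -0.08 and 0.14. The insulin receptor gene Insr differed by 0.10, 0.14 and -0.20, with limits from -0.56 to 0.51 over the 3 times, and Irs2 by -0.01, 0.14 and 0.02. Pemt, the phosphatidylethanolamine methyltransferase, differed by -0.03, -0.08 and -0.06, with limits from -0.23 to 0.12. Pparg differed by -0.06, -0.02 and -0.07, Cidec by 0.20, 0.08 and 0.06, and the clock genes Dbp by 0.57, 0.73 and 0.49 and Arntl by -0.20, -0.41 and -0.33.

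Some lists passed camera at none of the 3 times. The bile acid list (21 measured) held called members in both directions: Abcb4, a phospholipid exporter, rose at 7 days (log2 0.73) and 14 days (log2 0.54), Cyp7a1 fell at all 3 times, and Cyp7b1 fell at 7 and 21 days. Its smallest camera adjusted p was 0.122. In the drug-metabolising list (25 measured; smallest 0.13) Cyp2b9 rose at all 3 times, Ces2a and Gstp1 fell at 7 and 21 days, and Gstm3 fell at 21 days. At 21 days Suclg1 (log2 0.32) was higher in the tricarboxylic acid cycle, Kdsr (log2 0.44) in sphingolipid metabolism, and the glycolytic gene Tpi1 (log2 -0.29) was lower, without a camera call of their lists. The adipocyte list (smallest 0.11) had 1 called member, Pnpla3, higher at 7 days, and the neutrophil list (smallest 0.376) had Lcn2. Complexes II to IV (0.0812), ATP synthase (0.2), immediate early genes (0.945), cell cycle (0.215), inflammatory cytokines (0.213), stellate (0.502), cholangiocyte (0.797), lymphocyte (0.119) and erythroid (0.512) lists had 0 members called by limma over all genes. The value after each is its smallest camera adjusted p. The medians, means and tests of 6 lists at 7 days, 9 at 14 days and 5 at 21 days differed in sign, and none of these lists was called.

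The HFD times were then compared with each other. Between 14 and 7 days limma called 0 genes (451 with an unadjusted p under 0.05 where chance gives 899), and between 21 and 14 days 0 genes (715). Between 21 and 7 days it called 1 gene, Lcn2, which encodes the iron-binding lipocalin 2 (1283 at an unadjusted p under 0.05). Lcn2 stood at 4.08 ± 0.21 (SD, n = 18) in controls, 5.20 ± 0.29 (n = 8) at 7 days, 4.48 ± 0.41 at 14 days and 4.42 ± 0.30 at 21 days. It rose at 7 days against controls (log2 1.12, adjusted p = 6.70e-09) and fell by 0.77 on the log2 scale from 7 to 21 days (adjusted p = 0.0284), with 8 of 8 arrays at 21 days below the 7-day mean. It was also the 1 gene past the F test among the 3 times (adjusted p = 0.0204, with 792 genes at an unadjusted p under 0.05). This test called 0 genes with the replicate number as a block, with only the arrays compared, with the HFD arrays numbered 1 to 4 or 5 to 8 alone, and without any of HFD 7 days replicates 1, 2, 4, 7 or 8. The call from 7 to 21 days ended without any of 12 arrays, HFD 7 days replicates 1, 2, 4, 7 and 8 and HFD 21 days replicates 1 to 7 (adjusted p up to 0.149). It also ended with array weights, after quantile normalization, with the replicate block, with only the arrays compared, without the array that stands apart, and with the HFD arrays numbered 1 to 4 or 5 to 8 alone.

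As lists, PPAR-alpha targets were lower at 14 than at 7 days (median -0.20, camera adjusted p = 3.76e-09, adjusted p = 0.0266 with an estimated correlation; 0 of 26 members called). This was the only call of a list between HFD times that held with an estimated correlation. By fry its adjusted p was 0.146. Preset camera called 10 lists lower at 14 than at 7 days, 6 lower at 21 than at 14 days, and 20 lower and 1 higher at 21 than at 7 days. The smallest adjusted p was 0.551 for 21 against 14 days and 0.0873 for 21 against 7 days with an estimated correlation. The acinar markers were among those called lower at 21 days, with median changes of -1.18 against 14 days and -1.46 against 7 days.

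Calls against controls were largely shared in direction. At 7 and 14 days 111 genes were called in both (87 higher, 24 lower), at 7 and 21 days 97 (71 and 26), and at 14 and 21 days 85 (62 and 23), with 0 in opposite directions. Independent lists would share 1.05, 0.925 and 0.405 higher genes and 0.0693, 0.11 and 0.0742 lower genes. Simulated unchanged groups against the same controls shared 0 on average and at most 0. These groups held no changed gene, so this count does not show how far shared controls raise an overlap of changed genes. With the controls split, 54 and 61, 58 and 64, and 48 and 47 genes were shared. In all 3 comparisons 81 genes were called (62 higher, 19 lower). The count called at 7 days alone was 124, at 14 days alone 5 and at 21 days alone 25; the differences between times were tested above and 1 gene passed.

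Across genes, which are not independent replicates, the log2 changes at 7 and 14 days correlated with r = 0.766, those at 7 and 21 days with 0.558 and those at 14 and 21 days with 0.617. Simulated unchanged groups gave 0.289, 0.331 and 0.273 on average and up to 0.742, 0.803 and 0.737. With split controls r was 0.544 and 0.614, 0.326 and 0.469, and 0.378 and 0.467. The covariances were 0.0165, 0.0123 and 0.0115 against 0.00358, 0.00434 and 0.00353 on average in simulation (up to 0.0156, 0.0159 and 0.0198), a difference of 0.013, 0.00791 and 0.00798.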

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

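In this part, the tests of the list calls over the splits with an estimated correlation, and the tests over splits within the number sets, were chosen only after the results were seen. For each group of 8 HFD arrays and each named gene, the highest or lowest array was compared with the rest of its group, and 8 of 131 group and gene pairs (6.11%) had an array far from the others, where chance gives about 1 in 20. At 7 days Cyp7a1, the bile acid synthesis enzyme, was 5.69 in log2 on replicate 4 (the other arrays from 7.71 to 8.59), and Etnppl was 7.15 on the same array (others from 7.84 to 8.24). Without this array the fall of Cyp7a1 at 7 days was no longer called, as given above, whereas the call of Etnppl held. Also at 7 days, the carrier gene Slc25a47 was 10.37 on replicate 1 (others from 10.07 to 10.20). At 14 days the clock gene Arntl was 5.21 on replicate 7 (others from 3.80 to 4.28), and Rgs16 was 6.05 on replicate 3 (others from 7.72 to 9.19). At 21 days G6pc, the glucose-6-phosphatase gene, was 8.22 on replicate 6 (others from 9.33 to 10.12), and the glutathione transferase gene Gstm3 was 6.88 on the same array (others from 7.78 to 8.57). This array also correlated less with its group than the limit used for standing apart (0.892). Lcn2 was 5.08 on replicate 8 (others from 4.10 to 4.51).

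2 differences between HFD times passed a test of the difference itself. The median change of PPAR-alpha targets from 7 to 14 days was -0.199 in log2, and Lcn2 fell by 0.77 from 7 to 21 days. The HFD arrays numbered 5 to 8 differ from those numbered 1 to 4, so the splits were drawn again within these number sets, which keeps them balanced as in the real groups. Camera with an estimated correlation called at least 1 list between 14 and 7 days in 8 of 100 splits of either kind (real value 1, highest other 2, and 1 within the sets), so chance cannot be excluded for the PPAR-alpha difference. For Lcn2, 5 of 100 splits gave at least 1 gene between 21 and 7 days (real value 1, highest other 2), and 3 of 100 within the sets (highest other 27). The splits within the sets follow the real design, but they were chosen after the result was seen. The call of Lcn2 also ended without any of 12 arrays, so chance is not excluded for it.

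Probe sets outside the named genes also differed from controls in limma. Of 1469 probe sets with several gene symbols, 17 passed at 7 days (9 higher, 8 lower), 7 at 14 days (2 higher, 5 lower) and 9 at 21 days (2 higher, 7 lower). Of 11596 with no gene listed, 22 passed at 7 days (17 higher, 5 lower), 8 at 14 days (4 higher, 4 lower) and 15 at 21 days (11 higher, 4 lower). They were not assigned to genes here.

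The calls against controls were set beside 100 splits of the arrays into groups of the same sizes, the real one included. For genes, chance can be excluded at 7 days (1 of 100 splits with as many, real count 251, highest other 1), at 14 days (1 of 100, real 120, highest other 31) and at 21 days (2 of 100, real 126, highest other 415). For gene lists by preset camera, chance cannot be excluded at 7 days (6 of 100, real 19, highest other 24) or at 21 days (7 of 100, real 16, highest other 20). At 14 days 4 of 100 splits called as many (real 17, highest other 21), close to the other times, so chance is not firmly excluded there either. The other splits called a median of 8, 6 and 6 lists at 7, 14 and 21 days by this test, so its list calls alone carry little weight. With an estimated correlation only the real split reached 11, 7 and 6 lists, with highest other values of 2, 4 and 1.

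Between HFD times limma called 0 genes for 14 against 7 days and 0 for 21 against 14 days, with 451 and 715 genes at an unadjusted p under 0.05, so all 100 splits gave as many in each (highest other 1 and 724). For lists by preset camera the splits with as many were 16 of 100 (real 10, highest other 19), 43 of 100 (real 6, highest other 25) and 5 of 100 for 21 against 7 days (real 21, highest other 24), so chance cannot be excluded. For any difference among the 3 times 4 of 100 splits called at least 1 gene (real 1, highest other 200). The splits that called 415, 724 and 200 genes point to a structure of the samples other than the groups. Within the number sets, limma called as many genes in all 100 splits for 14 against 7 days and for 21 against 14 days (highest other 1 in each), and in 3 of 100 for any difference among the 3 times (real 1, highest other 15). Preset camera called as many lists within the sets in 17 of 100 (real 10, highest other 20), 51 of 100 (real 6, highest other 21) and 9 of 100 (real 21, highest other 25) for 14 against 7, 21 against 14 and 21 against 7 days. With an estimated correlation it called 0 lists for the latter 2 comparisons, so all 100 splits gave as many (highest other 2 and 1).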

How the results depend on the processing

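The tests with the HFD arrays numbered 1 to 4 or 5 to 8, the number set, Malat1 and the acinar mean were chosen only after the data were seen. Of 94 calls of named genes, none reversed under any setting run. 0 were lost with Malat1 or the number set as a covariate, with the mean of a gene's probe sets or without the dimmest genes, 2 with median centring, 2 with the acinar mean, 3 with trend and robust eBayes, 3 without the array that stands apart, 4 with array weights, 5 with quantile normalization and 8 with only the arrays compared. The number set is balanced within each HFD group, and Malat1 was level between groups. These covariates could hardly move a change against controls, so their 0 losses say little about robustness. With the HFD arrays numbered 1 to 4 23 were lost, and with 5 to 8 30, where fewer arrays are tested. At least 1 left-out array ended 18.

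Leaving out each array in turn gave 195 to 273 genes at 7 days, 81 to 126 at 14 days and 107 to 131 at 21 days, 0 to 1 for 14 against 7 days, 0 to 0 for 21 against 14 days, 0 to 1 for 21 against 7 days and 0 to 1 among the 3 times. For lists it gave 17 to 23, 13 to 19 and 13 to 16 against controls, and 5 to 15 (14 against 7 days), 4 to 16 (21 against 14) and 15 to 26 (21 against 7). The genes shared by all 3 comparisons were 66 to 83. The count for 14 against 7 days was 1 without HFD 7 days replicate 3, HFD 14 days replicate 5 or HFD 21 days replicate 8. The count among the 3 times was 0 without HFD 7 days replicate 1, 2, 4, 7 or 8.

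The cause was not tested for the values that follow, except where it is given. A fold change of at least 1.5 is stricter by construction and left 115, 62 and 68 genes at 7, 14 and 21 days and 42 shared by all 3. With array weights 605 genes passed at 7 days and 193 at 14 days, with 3 for 14 against 7 days, 0 for 21 against 7 days and 3 among the 3 times. The call between 21 and 7 days was also lost (0 genes) with only the arrays compared, with quantile normalization and without the array that stands apart, and the count among the 3 times was 0 with only the arrays compared. With quantile normalization 6 lists passed for 14 against 7 days and 9 for 21 against 7 days, and with median centring 6 for 14 against 7 days. Without added scaling 208 genes were higher and 43 lower at 7 days. They were 253 and 27 with median centring and 170 and 56 with quantile normalization. In the same order, the counts were 91 and 29, 75 and 20, and 92 and 39 at 14 days. At 21 days they were 80 and 46, 59 and 45, and 102 and 48. Rises stayed the majority each time. With the acinar mean as a covariate 13 lists passed for 21 against 14 days.

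With the HFD arrays numbered 1 to 4, 250 genes passed at 7 days, 69 at 14 days and 903 at 21 days, 0 for 21 against 7 days and 0 among the 3 times, with 49 shared. Lists numbered 17 for 14 against 7 days and 17 for 21 against 14 days. With those numbered 5 to 8 the genes were 144, 58 and 349, 0 for 21 against 7 days and 0 among the 3 times, with 49 shared, and the lists between times 6, 2 and 9. At 21 days the direction given by camera turned for 4 lists, mostly because a call was lost. The calls of mitochondrial carriers with the numbers 1 to 4 (median 0.0929, adjusted p = 0.964) and of acute phase proteins with 5 to 8 (median -0.0148, adjusted p = 0.976) were lost while the median kept its sign, and that of endothelial markers with 5 to 8 was lost (median 0.0171, adjusted p = 0.699). Immediate early genes, not called with all arrays, were called lower with 5 to 8 (median -0.198, adjusted p = 0.0199).

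With an estimated correlation camera called 11, 7 and 6 lists at 7, 14 and 21 days and 1, 0 and 0 between times (14 against 7, 21 against 14, 21 against 7), since a larger correlation widens its test. Fry, which does not compare a list with other genes, called 14, 8 and 6 lists, and 0, 0 and 0 between times.

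The replicate numbers do not pair the samples 1 to 1, since 22 of 48 same-numbered pairs had r over 0.1 and 5 of 32 arrays correlated best with their own number. Between HFD times the number sets tie arrays together: the median r was 0.205 for the same number (17 of 24 over 0.1), 0.186 for another number of the same set (47 of 72) and -0.167 for the other set (6 of 96). For controls with HFD arrays of the same number it was -0.0518 (5 of 24). With the replicate block 77 genes passed for 14 days HFD versus control, 227 for 7 days HFD versus control and 93 for 21 days HFD versus control, 0 for 21 against 7 days and 0 among the 3 times, and 18 named calls were lost.

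Arrays have no read depth. Dim genes lie near the background, and leaving them out kept each count of genes and lists within 1.5 times its value. The lists behind these counts changed in part: against controls, 9 list calls were lost and 5 gained.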

Other observations

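In this part the tests on the number sets and on the acinar markers, the naming of genes outside the lists, and the female-biased test without Cyp2b9 were chosen only after the results were seen. Of the genes called at all 3 times, 27 higher and 16 lower stood in none of the 37 lists. Among the higher ones, the apolipoprotein gene Apoa4 rose by 1.84, 1.49 and 1.32 in log2 at 7, 14 and 21 days, and Serpina7, thyroxine-binding globulin, by 1.73, 1.22 and 1.23. Fabp2, an intestinal-type fatty acid-binding protein gene, rose by 1.63, 1.26 and 1.02, the pantetheinase gene Vnn3 by 1.44, 1.27 and 1.22, and Pctp, the phosphatidylcholine transfer protein gene, by 1.17, 0.98 and 0.95. Ldha, lactate dehydrogenase A, rose by 0.54, 0.41 and 0.38. Among the lower ones, Csad of taurine synthesis changed by -0.93, -0.71 and -0.90, Cyp2c70, a bile acid hydroxylase, by -0.56, -0.59 and -0.69, and Gnmt, glycine N-methyltransferase, by -0.34, -0.36 and -0.29.

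Within the HFD groups, 4089 genes differed between the arrays numbered 5 to 8 (n = 12) and those numbered 1 to 4 (n = 12), 1891 higher and 2198 lower, and 42 and 8 of them by 2-fold or more. Malat1 stood at 9.13 ± 0.30 against 6.65 ± 0.61 (log2 difference 2.48, SE 0.15, limma adjusted p = 4.74e-11), with Clk1, a kinase of splicing factors, 1.72, Luc7l3 1.62 and Ccnl2 1.55 higher. Chance is excluded for this difference (1 of 100 splits within the groups with as many genes, highest other 1). The diet is argued against as its cause, since both sets held only HFD arrays, 4 of each HFD group. For Malat1 alone, the SD over controls was 0.915 of that over HFD arrays. More incompletely spliced nuclear RNA in the higher set may explain part of it: splicing regulators with retained introns, none of them named above, had a median difference of 0.59, with 15 of 18 higher and 0 lower by limma. They were chosen after splicing genes had been seen to lead the difference. With 1 value per gene, the rise shows more transcripts of this class, and unspliced RNA itself was not measured. A different time of day at sampling cannot be told apart from other causes, since 25% of the clock list (4 of 16) differed against 22.7% of all genes (Fisher p = 0.51). In single groups, 332, 247 and 2268 genes differed at 7, 14 and 21 days. Each set held 4 arrays of every HFD group, so the difference is not confounded with the HFD groups and widens the spread within them. Whether its size depends on time on the diet was not tested.

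Pancreatic acinar genes were high on some arrays of every group. Carboxypeptidase Cpb1 ran from 2.57 to 9.36 in log2 over the controls and up to 10.96 at 7 days, and trypsinogen Prss2 from 3.26 to 7.78 and up to 9.69. The diet is argued against as the cause, since 9 of 18 controls lay above the median acinar mean of the HFD arrays (4.97). The 13 acinar markers rose and fell together over the controls (median pairwise r = 0.959, lowest 0.75), so pancreatic tissue in the sampled piece is a candidate source. No other list held any of these 13 genes, and whether liver cells express some of them was not tested.

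As lists, female-biased liver genes tested higher and male-biased ones lower on HFD, with 5, 3 and 3 of 17 female-biased members higher and 5, 1 and 5 of 23 male-biased members lower at 7, 14 and 21 days. The male-biased call at 14 days did not hold with an estimated correlation (adjusted p = 0.083). Members shared with the PPAR-alpha and lipid lists are argued against as the whole cause for the female-biased list, which passed at 21 days without its 3 shared members (p = 0.0023, 14 left, camera with an estimated correlation). Without Cyp2b9 as well, the 13 members left had p = 0.032 at 7 days (2 rose), 0.106 at 14 days and 0.0381 at 21 days (0 called by limma over all genes at each of these 2), so much of the shift rests on Cyp2b9. The difference between the number sets cannot be told apart from other causes of the male-biased change at 21 days. Malat1 was level between groups, so its use as a covariate hardly moved the list (p = 0.000103) and decides nothing. With each number set against all controls the list pointed lower in both by camera with an estimated correlation. The median was -0.487 for the numbers 1 to 4 (p = 0.0031) and -0.234 for 5 to 8 (p = 0.0592), so the latter did not pass alone. Over all HFD arrays the list's median difference between the sets was -0.0386 (adjusted p = 0.997 by the same test). Activation of the constitutive androstane receptor cannot be told apart: 9 measured targets gave p = 0.726 with 0 higher and 1 lower (Gstm3), and its main target Cyp2b10 was not measured here. A steady trend with age is argued against for Cyp2b9 and Cyp7b1: the 7-day mice were as young as the youngest controls and the 21-day mice as old as the oldest, yet Cyp2b9 was higher at both times (log2 2.06 and 3.52, SE 0.37) and Cyp7b1 lower at both (-0.93 and -0.82, SE 0.17). The control mean of Cyp2b9 lay under the background percentile of 2.86, so its direction is surer than the size of its change. The diet itself stays open.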
